A study of Mus musculus with 57 samples.

How the data were processed

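RNA of the mouse brain was measured in 57 libraries of 16 groups, which combine 2 cell types (corticospinal neurons, CSN, and control cells), 2 genotypes (Sod1G86R and wild type) and 4 ages, with 2 to 4 libraries in each. Per the labels' protocols, total RNA was extracted with Trizol, cDNA was made with the SMART-Seq kit version 4 and 11 cycles of amplification, and libraries were made with Nextera XT and 12 cycles and sequenced on a HiSeq 4000 as paired reads of 50 bases. The kit does not mark strand, so reads of a gene and of its antisense or overlapping partner cannot be told apart. Per the series' design text, the authors aligned reads to GRCm38 with STAR 2.7.0 and counted them per gene of Ensembl 87 with STAR. The submitters' processing notes name edgeR and mm10 without a role or a version.

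The deposited table holds signal values that, per the labels, are normalised counts, for 45337 Ensembl genes, of which 44987 carry a symbol and 350 do not. The normalisation method is not given in the sources used here. The values of each library were whole multiples of 1 step within 0.001, so whole reads were recovered by dividing by that step, and the columns were taken as reads divided by a size factor per library. Recovered reads were 22.2 to 64.2 M per library. PCR copies were not marked by molecular identifiers, so reads are not independent molecules.

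Genes at or above 34.6 in at least 3 libraries of a fit were kept, where 34.6 is 1 ppm of the median column total, and log2(value + 34.6) was fitted with limma 3.58.1 in R 4.3.3 with a trended, robust prior and 1 coefficient per group. CSN and control cells were fitted apart for genotype and age, and together for CSN against control cells and for the difference of the genotype effect between them. Contrasts were Sod1G86R against wild type at each age and as the unweighted mean of the ages, genotype by age in CSN, the difference between cell types, CSN against control cells in wild type, and 105 against 30 days in wild type. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard deviations are between libraries of a group. Gene lists, 33 in all and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of each comparison. Over all comparisons camera called 176 of 462 list tests at the preset correlation, 2 with an estimated correlation and 60 by fry. Coordinates are those of GENCODE M21 on GRCm38.

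The genes named were set by rule before the data were examined. Sod1 and Creb3 are given in every comparison. Among genes that passed, with a mean of at least 346 in the higher group and a symbol that is not a predicted, clone or Riken name, the 10 largest rises and the 10 largest falls are named. Where fewer than 3 passed, the 3 smallest p-values per direction are given as values that did not pass. Up to 4 members with the smallest p are given from each list described. Items withheld for evaluation that these rules reach are not reported here.

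Library measures were compared between genotypes within ages by two-sided permutation tests with 100000 permutations, adjusted over 10 tests. Libraries of the same animal across cell types are paired by their labels. Their residual correlation was -0.318 to 0.282 over 25 pairs (median 0.0385), and over 0.1 in 7. The main fits of both cell types together took these libraries as independent. A block by animal was an alternative, with a consensus correlation of 0.0367. The lowest correlation between replicates was 0.886 and no library was a copy of another.

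Alternatives were a pseudocount 0.25 or 4 times as large, no filter, a filter of 173 in 8 libraries, quantile normalisation, TMM, array weights, covariates for detected genes, the glial marker score and the library number, only the libraries of the groups compared, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library. The covariates for the mitochondrial share and the receptor gene share, the fits without the 60-day or the 90-day libraries, and the ALS-linked list without Sod1 were chosen after the data had been seen. The fits were tested on simulated data with known changes. Of 100 genes changed by 2-fold and 100 by 4-fold, 75% and 98% were recovered for Sod1G86R in CSN over the ages, 35% and 75% at 90 days in CSN, 38% and 81% in control cells over the ages, 29% and 72% for the difference between cell types, and 1% and 10% in control cells at 60 days. False calls among all calls were 8 of 181, 2 of 112, 5 of 124, 3 of 104 and 0 of 11 in the same order. The highest numbers were 11 of 113 for age in wild-type CSN and 10 of 54 in control cells at 105 days. Genes were simulated independently of each other, so conditions shared within a library were not covered. Figures were drawn with matplotlib 3.10.9.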

Results

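RNA from cells of the mouse brain was measured by SMART-Seq sequencing in 57 libraries from 32 animals, of which 25 gave a library of each of the cell types. The cells were corticospinal neurons (CSN), which send their axons from the cortex to the spinal cord and degenerate in amyotrophic lateral sclerosis (ALS), and cells that the labels call control cells and describe no further. The animals were wild type or carried Sod1G86R, a mutant form of superoxide dismutase 1 that causes motor neuron disease in mice. They were sampled at 30, 60, 90 and 105 days, where the unit is a reading of plain numbers in the labels. In this order of ages, CSN libraries numbered 3, 4, 4 and 2 in Sod1G86R and 4 at each age in wild type. Control cells gave 3, 3, 4 and 4 libraries in Sod1G86R and 4, 2, 4 and 4 in wild type. Reads recovered from the normalised values ranged from 22.2 to 64.2 M per library, with medians of 37 and 31.5 M in Sod1G86R and wild-type CSN and 35 and 41.2 M in Sod1G86R and wild-type control cells. Levels below are normalised reads as mean ± SD, and fold changes are on the log2(value + 34.6) scale, which understates the change of low genes. Adjusted p-values are those of limma with Benjamini-Hochberg adjustment unless another tool is named.

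The transgene product was read out first, as a check of the labels. Sod1 (ENSMUSG00000022982, GRCm38 chromosome 16, 90220754 to 90226329, plus strand), which encodes the cytosolic superoxide dismutase, stood at 118700 ± 22700 in Sod1G86R CSN (n = 13) and 3230 ± 951 in wild-type CSN (n = 16), a 38.1-fold difference (log2 fold change 5.25, SE 0.134, adjusted p = 1.57e-22). In control cells the levels were 95960 ± 32300 (n = 14) and 3018 ± 790 (n = 14), 31.8-fold apart (log2 fold change 4.99, SE 0.17, adjusted p = 1.38e-18). Every Sod1G86R library lay above every wild-type library, between 80220 and 172200 against 1806 to 4562 in CSN, and between 38570 and 155500 against 1611 to 4244 in control cells. By age, Sod1 rose in CSN by 5.09, 5.38, 4.79 and 5.76 on the log2 scale and in control cells by 4.84, 5.43, 5.08 and 4.62. The genotype difference of Sod1 did not differ between the cell types (log2 difference 0.26, SE 0.217, adjusted p = 0.459; it took the opposite sign, -0.18, with quantile normalisation). Sod1 shares 650 bases with Scaf4 on the other strand, and the kit does not mark strand, but Scaf4 stood at 390.1 and 490.9 on average in Sod1G86R and wild-type CSN. Gm8566, a processed pseudogene copy of Sod1 on chromosome 6 (67205619 to 67206083) that was chosen after its values were seen, passed the test at each age in both cell types. Its values were 0.543% ± 0.233 of Sod1 in Sod1G86R CSN and 0.709% ± 0.234 in wild-type CSN, so they are uncertain because its reads cannot be separated from those of Sod1.

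**Figure D1:**
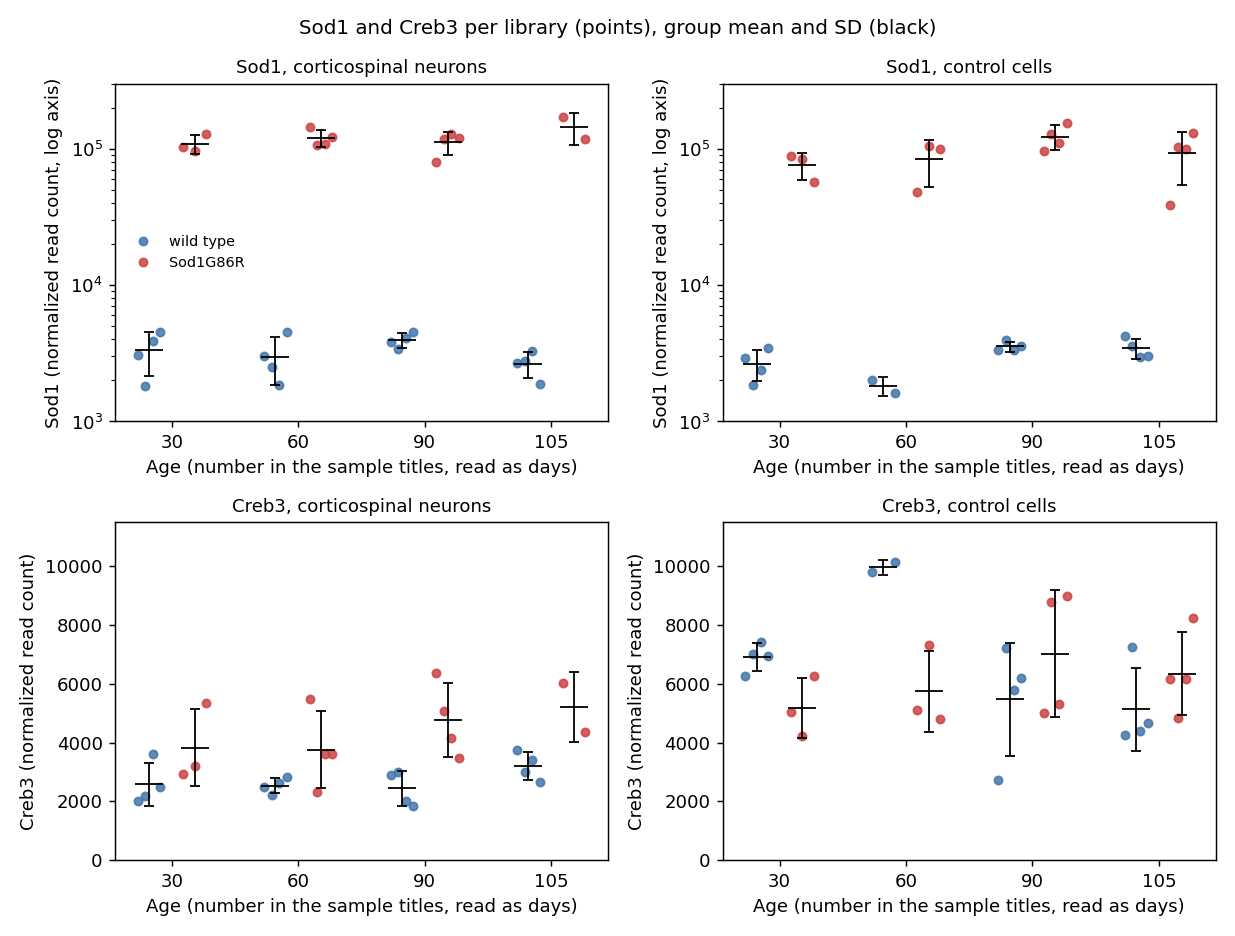
Normalised reads of Sod1 and Creb3 (vertical axes, Sod1 on a log axis) in each library by age in days (horizontal axis), with points for libraries and bars for group means. Sod1 in Sod1G86R CSN lies between 80220 and 172200, above the wild-type range of 1806 to 4562, and Creb3 averages 4310 in Sod1G86R CSN and 2694 in wild-type CSN.

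The identity of the cells was examined by comparing CSN with control cells in wild type over the 4 ages. Genes that mark CSN and other deep-layer projection neurons were far higher in CSN. Bcl11b (Ctip2), a transcription factor that specifies corticospinal identity, stood at 10680 ± 2020 in CSN (n = 16) and 244.1 ± 230 in control cells (n = 14; log2 fold change 5.83, adjusted p = 5.74e-27). Fezf2, which acts upstream of it, stood at 7569 ± 1610 and 233.3 ± 159 (log2 fold change 4.95, adjusted p = 4.08e-22). Of the 22 CSN markers fixed beforehand, 21 were higher in CSN, among them Crym (4.88) and Pcp4 (4.41), and Tle4 did not pass (-0.09, and 0.06 with quantile normalisation). Markers of upper-layer and callosal neurons went the other way, with 13 of 15 lower in CSN, such as the calcium buffer Calb1 (-6.02; 292.2 ± 269 against 23060 ± 13800), Rasgrf2 (-4.58) and Cux2 (-3.04), and 2 higher.

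Non-neuronal genes were lower in CSN than in control cells. All 12 astrocyte markers, 12 oligodendrocyte markers, 8 oligodendrocyte precursor markers and 14 microglia markers were lower, as were 12 of 14 endothelial and mural cell markers and 9 of 13 disease-associated microglia genes. Examples were the phagocyte receptor Trem2 (-3.88), Gja1 (-3.67), the myelin gene Mag (-3.50) and Cldn5 (-3.69). Interferon and antigen presentation genes were lower in 18 of 19, including B2m (-2.74) and H2-K1 (-3.17), and antioxidant genes in 15 of 19. Autophagy and lysosome genes (16 of 22 lower, 3 higher) and proteasome subunits (30 of 39 lower, 1 higher) were also lower in CSN. The share of mitochondrially encoded reads was 7.51% ± 2.39 in wild-type CSN and 1.19% ± 0.455 in wild-type control cells, with no overlap (lowest 4.559%, highest 2.104%), so these differences are not separated from it. Among immediate early genes, which respond to activity and to cell handling, 10 of 14 were lower and 2 higher, with Fos at -2.62 and Egr4 at 1.82. GABAergic markers were lower in 7 of 12, Gad1 among them (-2.37), while Pvalb was higher (2.82).

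Most genes of the axonal list and of the voltage-gated ion channel list were higher in CSN. The axonal cytoskeleton and transport list had 18 higher and 1 lower of 24, led by the neurofilament genes Nefh (5.28), Nefm (3.79), Ina (3.01) and Nefl (2.48). Ion channels had 17 higher and 5 lower of 24, with Scn1a (2.16) higher and Kcnc2 (-4.03) lower. Presynaptic genes had 13 higher and 1 lower of 20, postsynaptic genes 16 and 1 of 22, pan-neuronal genes 13 and 0 of 15, and glutamatergic markers 6 and 3 of 10. All 12 genes of the mitochondrial genome in the oxidative phosphorylation list were higher, such as mt-Cytb (2.56). In all, 12405 of 22032 genes passed, 5910 higher and 6495 lower in CSN, 4860 of them by over 2-fold. Of the 21 lists called by camera with the preset correlation, the CSN markers (adjusted p = 3.3e-06) and the axonal cytoskeleton genes (adjusted p = 0.036) also passed with an estimated correlation, and the other lists named here had adjusted p = 0.051 to 0.34 with an estimated correlation. Counts adjusted over each list alone were the same for these lists except endothelial and mural cell markers, with 13 lower. The named genes kept their calls without any 1 library.

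The effect of Sod1G86R in CSN was taken first as the mean over the 4 ages. Among the genes named by rule, the largest rise after Sod1 was in Ndfip1, an adaptor of Nedd4-family ubiquitin ligases, at 54840 ± 22400 in Sod1G86R (n = 13) and 22550 ± 8120 in wild type (n = 16; log2 fold change 1.27, SE 0.204, adjusted p = 0.000291, above the wild-type mean in 11 of 13). Also among the 10 largest rises were Hsd11b1, which regenerates active glucocorticoids (1.18), Smyd2, a lysine methyltransferase (1.16; 3168 ± 1010 against 1476 ± 575), the calcium buffer Pvalb (1.16), Atp6v0c, a proton-channel subunit of the vacuolar ATPase (1.15; 6501 ± 2200 against 2945 ± 1030, adjusted p = 0.000351), Gnb5 (1.15), Wee1 (1.14), the mitochondrial phosphatase Pgam5 (1.12) and Lhfpl5 (1.17). Among the largest falls, Fnbp1l, a regulator of actin and membrane curvature, stood at 3269 ± 797 and 7910 ± 1560 (-1.31, SE 0.1, adjusted p = 6.22e-10, below in 13 of 13), and Ndst3, a heparan sulfate modifying enzyme, at 1907 ± 457 and 4561 ± 790 (-1.31, SE 0.118, adjusted p = 2.79e-08).

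Of the falls, Fnbp1l, Ndst3, Ugt8a (-1.56), Arhgap29 (-1.16), Cnn3 (-1.09), Rwdd3 (-1.08) and Sec24d (-1.06) lie in 1 stretch of chromosome 3, from 118430324 to 126846326 (8.42 Mb, GRCm38). This stretch was chosen after its values were seen. All 32 of its genes above the level set for the scan had lower values in Sod1G86R CSN, with a median log2 fold change of -0.97, and 28 of them passed the test. In control cells the 32 genes above that level were largely but not all the same. Their median was -0.92, 29 of 32 lay below 0 and 7 fell. In the 5 Mb before and after it the medians were -0.04 and -0.14 in CSN and -0.08 and -0.10 in control cells. The remaining large falls were Ctsc (-1.62), Gpr34 (-1.50) and Rnase4 (-1.48), of which Gpr34 is a microglia marker and Ctsc encodes a lysosomal protease. Ctsc lost its call without any 1 of 20 of the 29 libraries (adjusted p up to 0.134), Gpr34 without any 1 of 14 (up to 0.123) and Cnn3 without Sod1G86R 105-day replicate 9 (0.109).

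**Figure D2:**
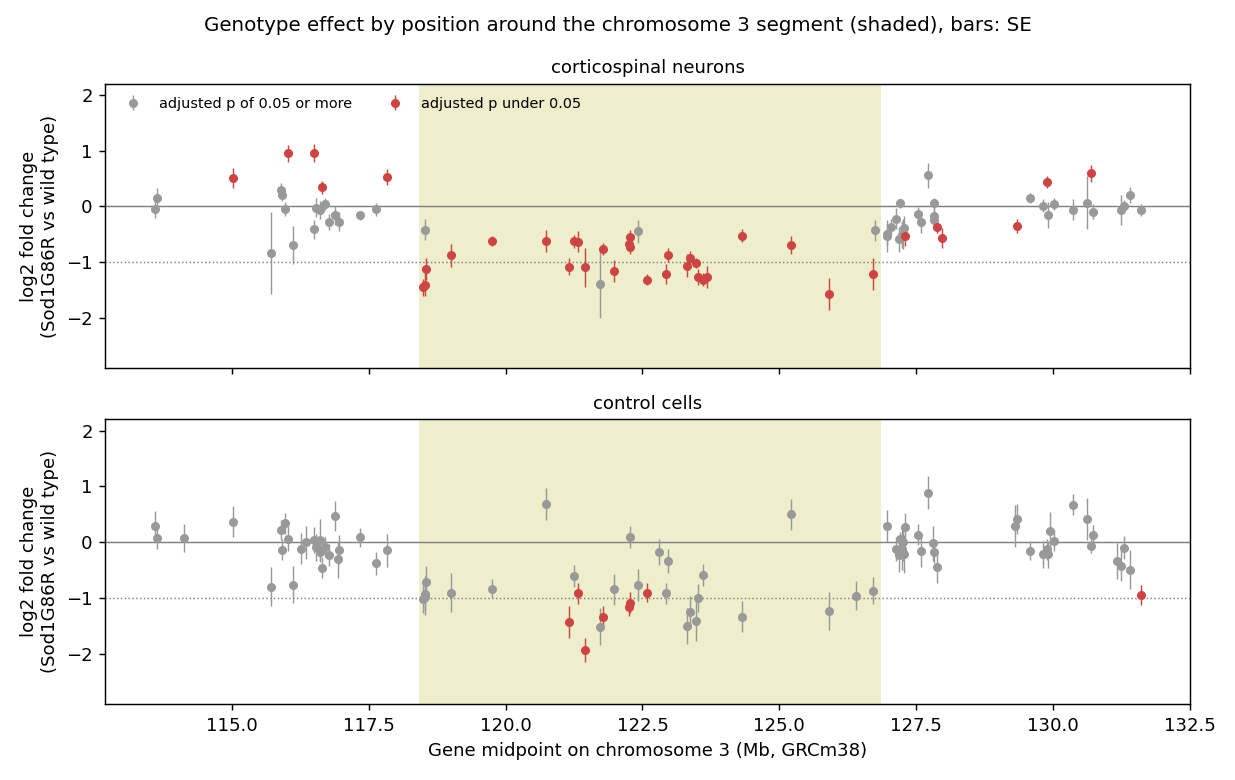
Log2 fold change of Sod1G86R against wild type (vertical axes, mean of the 4 ages) for genes along chromosome 3 by position in Mb of GRCm38 (horizontal axis), in CSN and in control cells, 1 point per gene. The genes between 118430324 and 126846326 have medians of -0.97 in CSN and -0.92 in control cells.

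Some protein turnover genes rose in Sod1G86R CSN. Of 38 measured proteasome subunits, 32 rose and 6 did not pass (34 when adjusted over the list alone), for example Psmd8 (0.80; 7034 ± 1820 against 4092 ± 997), Psmd13 (0.78) and Psmc2 (0.64). The list passed camera (adjusted p = 2.2e-18), with adjusted p = 0.56 with an estimated correlation. Of 22 autophagy and lysosome genes, 11 rose (12 when adjusted over the list alone), including the cathepsin Ctsb (0.76; 40240 ± 13300 against 23000 ± 5160), the autophagy receptor Sqstm1 (0.61) and Map1lc3b (0.78; camera adjusted p = 0.00016, adjusted p = 0.56 with an estimated correlation). In both lists these counts stood beside a lower share of mitochondrially encoded reads in Sod1G86R CSN, 4.90% ± 1.77 (n = 13) against 7.51% ± 2.39 (n = 16; permutation p = 0.00045, adjusted p = 0.0045 over 10 library measures). With the log2 of that share as a covariate, no member of either list passed. The medians fell from 0.56 to 0.27 for the proteasome and from 0.33 to 0.19 for autophagy and lysosome genes. Camera at the preset correlation still called both lists with that covariate (adjusted p = 1.7e-13 and 0.022). Without the covariate, fry gave adjusted p = 0.00035 and 0.0072. With quantile normalisation the medians were 0.32 and 0.17.

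Some secretory pathway genes rose as well. Of 27 ER-to-Golgi trafficking genes, 13 rose, such as the coatomer subunits Cope (0.71) and Copg1 (0.48), and 1 fell, Sec24d, which lies in the chromosome 3 stretch (14 and 1 when adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.56 with an estimated correlation). Of 26 genes of ER stress and the unfolded protein response, 8 rose, with the same count when adjusted over the list alone. They included Asns, an amino acid response gene (0.92; 11260 ± 4740 against 5856 ± 1750), Herpud1 (0.75; 4596 ± 1510 against 2725 ± 754), Xbp1 (0.78) and the chaperone Dnajb9 (0.62), and the list had camera adjusted p = 0.0052 and adjusted p = 0.56 with an estimated correlation. In the CREB3 family list, Creb3, Herpud1 and Arf4 (0.41) rose and Crebzf fell (-0.27) of 10 measured, with the same counts when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.46). With the mitochondrial share, lower in Sod1G86R CSN, as a covariate, no member of these lists passed in limma. The medians went from 0.26 to 0.12 for ER-to-Golgi genes and from 0.16 to 0.06 for the unfolded protein response (0.13 and 0.09 with quantile normalisation). Camera at the preset correlation gave these 2 lists adjusted p = 0.14 and 0.35 with the covariate. Without it, fry gave adjusted p = 0.011 and 0.023. Arf4 lost its call without any 1 of 8 of the 29 libraries (adjusted p up to 0.0795), and Crebzf without Sod1G86R 105-day replicate 13 (0.125) or 30-day replicate 6 (0.0601).

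Oxidative phosphorylation genes split by genome. Of 78 nuclear genes, 33 rose and none fell (38 when adjusted over the list alone), such as Uqcrc1 (1.06; 40050 ± 12300 against 19500 ± 5390, adjusted p = 8.66e-05), Ndufa9 (1.03) and Ndufv1 (0.99). The list had camera adjusted p = 6.1e-14 and adjusted p = 0.57 with an estimated correlation. Of 12 genes of the mitochondrial genome, 9 fell (11 when adjusted over the list alone), among them mt-Atp6 (-0.62) and mt-Co2 (-0.83), with camera adjusted p = 8.8e-05 and adjusted p = 0.56 with an estimated correlation. The mitochondrial genome list is part of the mitochondrial share itself. With that share as a covariate the nuclear list had a median of 0.08, from 0.39, and no member that passed in limma. With quantile normalisation its median was 0.13. Camera at the preset correlation still called the nuclear list with the covariate (adjusted p = 0.004), and fry gave adjusted p = 0.039 without it.

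Among neuronal lists, CSN markers had 6 higher of 22, such as Diaph3 (0.79) and Parm1 (0.51), and axonal cytoskeleton genes 5 higher of 24, such as the tubulin Tuba4a (0.82; 23610 ± 7530 against 13590 ± 4100), Tubb4a (0.60) and Stmn2 (0.34). ALS-linked genes without Sod1, the gene of the transgene, had 5 higher, Tuba4a and Sqstm1 among them, and 1 lower, Unc13a (-0.34), of 25. Counts were the same when adjusted over each list alone. Camera gave adjusted p = 0.015 and 0.024 for the CSN markers and axonal genes, and adjusted p = 0.57 and 0.56 with an estimated correlation. Fry gave them adjusted p = 0.03 and 0.02. The ALS-linked list did not pass camera without Sod1 (adjusted p = 0.18). With the mitochondrial share as a covariate 0 of 22 CSN markers and 0 of 24 axonal genes passed in limma, the medians went from 0.17 to 0.09 and from 0.11 to 0.09, and camera gave adjusted p = 0.12 and 0.031. The median of each of the 3 lists was above 0 (0.17, 0.11 and 0.11) but below 0 with quantile normalisation (-0.01, -0.14 and -0.08), where Stmn2 also turned to -0.01, and Unc13a lost its call without Sod1G86R 105-day replicate 13 (adjusted p = 0.0668).

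Some markers of glia fell in Sod1G86R CSN. Of 14 microglia markers 3 fell, Aif1 (-0.99; 154.4 ± 73.2 against 344.2 ± 159), Cx3cr1 (-0.74) and Gpr34, and all 14 had values below 0 (12 lower when adjusted over the list alone; camera adjusted p = 8.8e-05, adjusted p = 0.56 with an estimated correlation). Of 8 oligodendrocyte precursor markers 2 fell, Pdgfra (-0.73) and Gpr17 (-0.86), at low mean levels (34.84 against 80.12 and 11.84 against 69.29). Of 12 oligodendrocyte markers 1 fell, Ugt8a, which lies in the chromosome 3 stretch, and the others did not pass (median -0.92). Their camera adjusted p-values were 0.015 and 0.006, and their adjusted p = 0.56 and 0.65 with an estimated correlation. Of 12 astrocyte markers 0 passed in limma, over all genes or adjusted over the list alone (median -0.23, camera adjusted p = 0.44), and at 90 days the medians of astrocyte and oligodendrocyte markers were above 0 (0.82 and 0.56). With the mitochondrial share as a covariate no member of these 4 lists passed in limma. Camera at the preset correlation with it gave microglia, precursor, oligodendrocyte and astrocyte markers adjusted p = 6.9e-05, 0.0057, 0.0052 and 0.12. Without the covariate, fry gave microglia, precursor and oligodendrocyte markers adjusted p = 0.024, 0.025 and 0.12. The mean log2 level of astrocyte, oligodendrocyte and microglia markers per library was 8.78 ± 0.844 in Sod1G86R CSN and 9.46 ± 0.862 in wild-type CSN (permutation p = 0.0479, adjusted p = 0.0669).

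In total 3643 of 19093 genes passed in CSN over the 4 ages, 2438 higher and 1205 lower, 71 of them by over 2-fold. The count was 25 with the mitochondrial share as a covariate, 39 with the share of olfactory, vomeronasal and taste receptor genes, 1582 with the number of detected genes, 2173 with no filter, 1118 without the 90-day libraries and 2222 without Sod1G86R 105-day replicate 13. Those receptor genes, which these cells are not known to use, made up 119.5 ± 61.4 ppm of the reads in Sod1G86R and 199.6 ± 78.8 in wild type (permutation p = 0.00175, adjusted p = 0.00753).

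**Figure D3:**
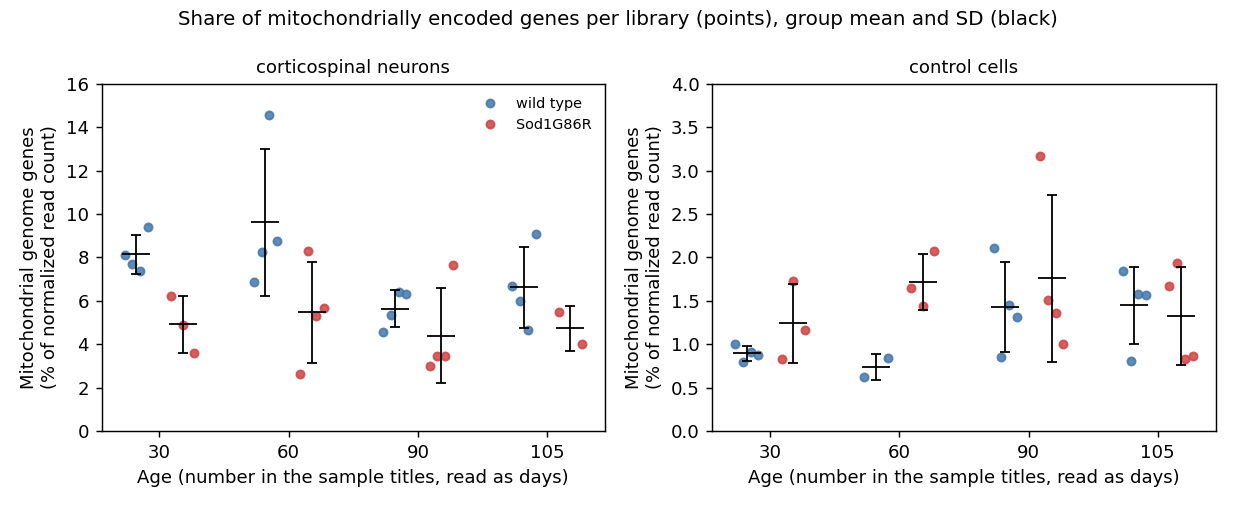
Share of normalised reads on mitochondrially encoded genes in percent (vertical axis) in each library by age in days (horizontal axis), with points for libraries and bars for group means. In CSN the Sod1G86R libraries average 4.90% and the wild-type libraries 7.51%.

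Creb3 is the gene named in the title of the series. It encodes a transcription factor anchored in the endoplasmic reticulum membrane and released by cleavage (ENSMUSG00000028466, GRCm38 chromosome 4, 43562332 to 43567060, plus strand). In CSN it rose over the 4 ages, from 2694 ± 574 in wild type (n = 16) to 4310 ± 1260 in Sod1G86R (n = 13), a 1.59-fold change (log2 fold change 0.67, SE 0.129, adjusted p = 0.000831) with 12 of 13 above the wild-type mean. In control cells it stood at 6163 ± 1580 and 6436 ± 2040 (n = 14 each) and did not pass (-0.14, SE 0.155, adjusted p = 0.729), with the opposite sign in 5 of the alternatives (0.02 to 0.10). The difference between these effects passed (0.81, SE 0.201, adjusted p = 0.0202). In wild type Creb3 was lower in CSN than in control cells (-1.29, SE 0.138, adjusted p = 3.43e-11).

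By age, Creb3 in CSN was 3835 ± 1320 against 2580 ± 721 at 30 days (n = 3 and 4; 0.55, adjusted p = 0.347), 3759 ± 1310 against 2543 ± 253 at 60 days (n = 4 and 4; 0.50, adjusted p = 0.628), 4770 ± 1250 against 2442 ± 598 at 90 days (n = 4 and 4; 0.95, adjusted p = 0.0261) and 5202 ± 1190 against 3212 ± 467 at 105 days (n = 2 and 4; 0.68, adjusted p = 0.617). A difference of its effect between ages did not pass (adjusted p = 1). That test recovered 14% of simulated 2-fold changes at 90 days, so equal effects are not shown. In control cells the log2 fold changes of Creb3 were -0.43, -0.82, 0.39 and 0.31 in the same order and none passed.

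The rise of Creb3 over the ages kept its call without any 1 library (adjusted p 0.00023 to 0.00764) and with the glial marker score as a covariate (0.61, adjusted p = 0.00551), and lost it with the mitochondrial share (0.35, SE 0.135, adjusted p = 0.326) and the receptor gene share (0.43, adjusted p = 0.189). At 90 days it lost the call without any 1 of 5 libraries, Sod1G86R replicate 3, 5 or 6 or wild-type replicate 7 or 9 (adjusted p = 0.108, 0.0845, 0.0826, 0.105 and 0.126), and also with no filter, quantile normalisation or either covariate (adjusted p = 0.0909, 0.0544, 0.0896 and 0.566). The difference between cell types was lost without CSN Sod1G86R 105-day replicate 13 (adjusted p = 0.0523), with quantile normalisation (0.0851), with the number of detected genes (0.411), the mitochondrial share (0.25, adjusted p = 0.992) or the receptor gene share (adjusted p = 0.706), and without the 60-day libraries (adjusted p = 0.278). Creb3 overlaps the ends of Tln1 and Gba2 on the other strand, whose reads the kit cannot tell apart, and neither passed in CSN (-0.04, adjusted p = 0.861, and 0.07, adjusted p = 0.642).

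At 30 days, the youngest age, 3 of 19093 genes separated Sod1G86R from wild-type CSN. Besides Sod1 and Gm8566, Fnbp1l fell from 7102 ± 1140 (n = 4) to 2386 ± 167 (n = 3; -1.55, SE 0.2, adjusted p = 9.24e-05). Next by p were Sfmbt2 (1.48), Aamp (1.04), Dph7 (1.32) and Ndst3 (-1.20), each with adjusted p = 0.0677, Xndc1 (-1.18, adjusted p = 0.0788) and Gclm (-0.90, adjusted p = 0.0853). Proteasome subunits had a median of 0.61 and 0 of 38 passed over all genes (26 when adjusted over the list alone), microglia markers -1.53 and 0 of 14 (3 lower), while 2569 genes had an unadjusted p under 0.05. The mitochondrial share was 4.92% ± 1.32 (n = 3) against 8.15% ± 0.893 (n = 4) at this age. Without wild-type replicate 4 the count was 42, and Sfmbt2, Aamp, Dph7, Ndst3 and Xndc1 passed (adjusted p 0.0442 to 0.0452). Sfmbt2 also passed without wild-type replicate 3 (adjusted p = 0.00202) and Aamp without Sod1G86R replicate 3 (adjusted p = 0.018), where the count was 8, and DESeq2 gave 284.

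At 60 days 6 genes passed in CSN. Ndst3 fell from 4739 ± 958 to 1827 ± 378 (-1.36, adjusted p = 0.00422, n = 4 each) and Fnbp1l from 9433 ± 1870 to 3968 ± 900 (adjusted p = 0.00135). Abcd3, a peroxisomal transporter (-1.05, adjusted p = 0.037), and Gm26871, a predicted transcript chosen after its values were seen (-1.46, adjusted p = 0.037), also fell. These 4 genes lie in the chromosome 3 stretch, and the others were Sod1 and Gm8566. Nuclear oxidative phosphorylation genes had a median of 0.43 and proteasome subunits of 0.43, with 0 of 78 and 0 of 38 passed (0 and 7 when adjusted over the list alone), among 1501 genes with an unadjusted p under 0.05. The mitochondrial share was 5.49% ± 2.33 against 9.61% ± 3.39 (n = 4 each). The count was 3 with the mitochondrial share as a covariate, and 3 without wild-type replicate 2, where Ndst3 lost its call (adjusted p = 0.0556). Abcd3 and Gm26871 lost their calls without any 1 of 5 and of 6 of the 8 libraries (adjusted p up to 0.298 and 0.297), and DESeq2 gave 14.

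At 90 days 928 genes passed in CSN, 664 higher and 264 lower, 367 of them by over 2-fold. Crbn, the substrate receptor of a ubiquitin ligase, rose from 2195 ± 712 to 6831 ± 2070 (1.62, SE 0.288, adjusted p = 0.0135, n = 4 each), the histamine-degrading enzyme Hnmt by 1.61 (adjusted p = 0.0167) and Ndfip1 from 21800 ± 10400 to 68970 ± 25500 (1.71, adjusted p = 0.0236). Further rises were Hsd11b1 (1.80), Zdhhc16 (1.79), Kbtbd4 (1.77), Pgam5 (1.71), Ak8 (1.68) and Dph1 (1.63). Prss12, a neuronal serine protease in the chromosome 3 stretch, fell from 1866 ± 241 to 772.5 ± 96.6 (-1.24, adjusted p = 0.000591), the postsynaptic scaffold Shank1 from 2640 ± 1360 to 1017 ± 357 (-1.29), and Celf5 by 1.24. The noncoding Mir6240 (-2.52) and CT010467.1 (-2.02), mt-Co2 (-1.74), Pou1f1 (-1.68), Tnrc18, Pdap1 (-1.22) and Pbld2 (-1.21) fell as well.

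By list at 90 days, 9 of 38 proteasome subunits rose, such as Psmd5 (1.22) and Psma1 (1.03; 18 when adjusted over the list alone). Of 22 autophagy and lysosome genes 4 rose (9 when adjusted over the list alone), Lamp1 (0.94; 12390 ± 1520 against 6444 ± 928), Map1lc3b (1.17), Ctsb (1.01) and Ctsl (0.62). Of 27 ER-to-Golgi genes 4 rose (12 when adjusted over the list alone), Copg1 and Sec23b among them, and of 18 cholesterol synthesis genes 3 rose (7 when adjusted over the list alone), led by Nsdhl (1.28). Nuclear oxidative phosphorylation had 11 of 78 higher (16 when adjusted over the list alone), such as Uqcrc1 (1.32) and Sdha (0.99), around a median of 0.12 that turned to -0.17 with quantile normalisation. Lower were 1 of 14 immediate early genes, Npas4 (-1.17), and 1 of 12 mitochondrial genome genes, mt-Co2 (1 and 3 when adjusted over the list alone). Of 80 ribosomal protein genes none passed in limma, also when adjusted over the list alone, and 75 had values below 0 (median -0.51). Camera called these 8 lists at adjusted p 1.5e-10 to 0.045, and with an estimated correlation they had adjusted p = 0.72 to 1.

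At this age the mitochondrial share was 4.39% ± 2.18 in Sod1G86R and 5.65% ± 0.871 in wild type (n = 4 each), and receptor genes stood at 84.8 ± 22.6 and 200 ± 113 ppm of the reads. The count was 5 and 4 with these shares as covariates, 4 with no filter, and 440 with quantile normalisation, where 239 were higher and 201 lower. It was 4 without any 1 of Sod1G86R replicates 3, 5 and 6 or wild-type replicates 7 and 9. It was 1983 without Sod1G86R replicate 8 and 1650 without wild-type replicate 6. Every gene named at 90 days other than Sod1 and Prss12 lost its call without any 1 of those 5 libraries, and Ctsl also without wild-type replicate 3 (adjusted p = 0.0636).

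At 105 days, with 2 Sod1G86R libraries, 4 genes passed in CSN. Ndst3 stood at 1509 ± 754 (n = 2) and 4560 ± 800 (n = 4; -1.65, adjusted p = 0.0066), Fnbp1l at 3169 ± 826 and 7527 ± 1510 (-1.24, adjusted p = 0.0326), and the others were Sod1 and Gm8566. Microglia markers had a median of -1.33 and proteasome subunits of 0.55, with 0 of 14 and 0 of 38 passed over all genes or adjusted over the list alone, and the mitochondrial share was 4.74% ± 1.04 against 6.62% ± 1.86. Without Sod1G86R replicate 13 the count was 2 and Ndst3 lost its call (adjusted p = 0.997), as Fnbp1l did without any 1 of 5 of the 6 libraries (adjusted p 0.0725 to 0.997). The tools edgeR and DESeq2 gave 2 and 23 genes. A test of whether the genotype effect differed between ages passed for 0 of 19093 genes in limma, with 591 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2. Differences in count between ages are therefore not shown to be differences in effect.

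In control cells over the 4 ages, 15 of 20944 genes passed, 3 higher and 12 lower. Gad2, which makes the transmitter GABA, rose from 723.8 ± 890 in wild type to 2215 ± 1650 in Sod1G86R (n = 14 each; 2.28, SE 0.447, adjusted p = 0.0351, above in 13 of 14), beside Sod1 and Gm8566. Cnn3, an actin-binding protein, fell from 10950 ± 8260 to 2750 ± 1220 (-1.93, adjusted p = 6.69e-06) and Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, from 2466 ± 645 to 1119 ± 284 (-1.16, adjusted p = 0.000213, below in 14 of 14). Traf4 fell by 2.61 (733.5 ± 810 to 77.29 ± 92.6, adjusted p = 0.00792), and Igsf21 (-1.62), Rwdd3 (-1.43), Abcd3 (-1.34), Dnttip2 (-1.08), Papss1 (-0.95), Sdc2 (-0.94) and Alg14 (-0.91) were lower too, as were Fnbp1l (-0.90) and the proteoglycan gene Cspg5 (-0.83), each chosen after its values were seen. Cnn3, Gclm, Rwdd3, Abcd3, Dnttip2, Alg14 and Fnbp1l lie in the chromosome 3 stretch.

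In the lists, 1 of 12 GABAergic markers rose over all genes and 5 when adjusted over the list alone, with Gad1 at 1.96 (adjusted p = 0.073, and 0.017 and 0.0367 without Sod1G86R 60-day replicate 3 or wild-type 105-day replicate 11), camera adjusted p = 9.1e-06 and adjusted p = 0.2 with an estimated correlation. Among antioxidant genes only Gclm of 19 fell (3 lower when adjusted over the list alone). Astrocyte, oligodendrocyte precursor, oligodendrocyte and microglia markers had medians of -0.61, -0.90, -0.46 and -0.46, and in limma 0 of 12, 8, 12 and 14 passed over all genes (6, 3, 2 and 0 lower when adjusted over the list alone). Genes of the mitochondrial genome had a median of 0.41 with 0 of 11 passed, over all genes or adjusted over the list alone. Camera called 18 lists, of which 0 passed with an estimated correlation (lowest adjusted p = 0.2) or by fry. The glial marker score was 12.16 ± 0.559 in Sod1G86R and 12.56 ± 0.991 in wild type, and the mitochondrial share 1.52% ± 0.625 against 1.19% ± 0.455 (n = 14 each; permutation p = 0.0561 and 0.0602, each adjusted p = 0.0669).

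Of these calls, Gad2, Igsf21, Rwdd3 and Alg14 were each lost without any 1 of 13 to 19 of the 28 libraries (adjusted p up to 0.264), and Fnbp1l and Cspg5 without any 1 of 9 and of 10 (up to 0.217 and 0.256). So were Papss1 without Sod1G86R 30-day replicate 3 (0.0574) or wild-type 60-day replicate 1 (0.217), Traf4 without the latter (0.148), and Dnttip2 and Sdc2 without wild-type 60-day replicate 2 (0.0589 and 0.0703). The count was 58 without wild-type 105-day replicate 13, 28 without replicate 9 of that group, 37 without wild-type 90-day replicate 3, 33 without Sod1G86R 30-day replicate 2, and 7 and 9 without wild-type 60-day replicates 1 and 2. It was 8 without the 60-day libraries, 6 with the mitochondrial share and 5 with the number of detected genes as a covariate, and 174 in DESeq2.

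By age, control cells at 30, 90 and 105 days each had 2 genes that passed, Sod1 and Gm8566. Values that did not pass included Cnn3 (-2.26, adjusted p = 0.0566), Abcd3 (-1.92), Sdc2 (-1.54), Clec7a (2.68) and Fkbp5 (2.36) at 30 days. At 90 days they included Fnbp1l (-1.34), Pqlc2 (-1.85), Prelp (-2.57), Prox1 (2.17), Arhgap12 (1.37) and Tmod3 (1.08), and at 105 days Alg14 (-1.46), Ndst3 (-1.46), Tent2 (-1.26), Fbxw9 (2.13), Cavin2 (1.62) and Ppie (1.24). GABAergic markers had medians of 1.04, 0.71 and 1.06 at these ages, and 0 of 12 passed in limma at each, over all genes or adjusted over the list alone, with camera adjusted p = 1.9e-05, 0.0034 and 0.001 and adjusted p = 0.29, 0.96 and 0.71 with an estimated correlation. Unadjusted p-values under 0.05 numbered 1100, 589 and 932, and DESeq2 gave 41, 8 and 9 genes. At 30 days the count was 4 without Sod1G86R replicate 2 or 3 or wild-type replicate 4, and 5 without Sod1G86R replicate 4, where Cnn3 passed (adjusted p = 0.0422), and Clec7a passed without Sod1G86R replicate 3 (adjusted p = 0.00016).

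At 60 days control cells had 293 genes that passed, 22 higher and 271 lower, in a comparison of 3 Sod1G86R with 2 wild-type libraries. The 2 wild-type libraries had the highest glial marker scores of all 57 libraries, 14.02 and 14.17, with 13.36 in the next. Some glial genes fell. Aldh1l1, an astrocyte folate enzyme, stood at 271.1 ± 100 (n = 3) and 2048 in wild type (n = 2; -2.82, adjusted p = 0.0247), the microglial gene Tmem119 at 1837 ± 613 and 20770 ± 3040 (-3.52) and the myelin gene Mag at 2166 ± 1980 and 20330 ± 4520 (-3.60). The largest falls were Fzd9 (-4.79), the immediate early gene Jun (-4.65), Traf4 (-4.63), Slc7a10 (-4.46), Btbd17 (-4.37), Mfge8 (-4.34), Pdgfra (-4.28), Bckdha (-4.21), Rpe65 (-4.07) and Slc27a1 (-4.05). Besides Sod1, the named rises were Rn7sk (3.20), Serpina3h (2.50), Pkib (1.80), the postsynaptic scaffold Homer1 (1.73; 10210 ± 780 against 3069 ± 567) and the chaperone Hsp90aa1 (1.43).

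By list at 60 days in control cells, lower genes numbered 2 of 12 astrocyte markers, 1 of 12 oligodendrocyte, 1 of 8 oligodendrocyte precursor and 1 of 14 microglia markers (9, 3, 7 and 5 when adjusted over the list alone). They also numbered 4 of 22 autophagy and lysosome genes, Psap, Hexa, Ctsd and Grn, 2 of 19 antioxidant genes, Gclm and Keap1, 2 of 18 cholesterol synthesis genes and 1 of 26 unfolded protein response genes, Pdia4 (11, 4, 5 and 1 when adjusted over the list alone). Of 82 nuclear oxidative phosphorylation genes 1 fell, Sdha (-1.85), around a median of 0.69 (21 higher and 2 lower when adjusted over the list alone). In limma 0 of 79 ribosomal protein genes (median 0.85) and 0 of 11 mitochondrial genome genes (median 1.25) passed over all genes (0 and 8 higher when adjusted over the list alone). These lists had adjusted p = 0.49 to 0.57 with an estimated correlation. The share of higher calls moved from 7.51% to 34% with quantile normalisation (70 higher, 136 lower), which moved the median of all genes from -0.05 to 0.10.

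The wild-type control cells at 60 days had a mitochondrial share of 0.738% ± 0.154 (n = 2) against 1.72% ± 0.321 in Sod1G86R (n = 3), and receptor genes at 85.3 ± 64.6 against 623 ± 275 ppm of the reads. The count of 293 was 2 with the glial marker score as a covariate, 4 with the mitochondrial share, 6 with the number of detected genes, 84 in edgeR and 2239 in DESeq2. It was 1 without wild-type replicate 1, 15 without wild-type replicate 2, and 52, 501 and 174 without Sod1G86R replicates 3, 5 and 7. Every gene named at this age other than Sod1 lost its call without at least 1 of these 5 libraries.

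Whether the genotype effect differed between CSN and control cells was tested directly, as the mean over ages. It passed for 1380 of 22032 genes, 846 more positive and 534 more negative in CSN, 495 of them by over 2-fold on the log2 scale of the difference. Psmd13 had a difference of 1.29 (SE 0.282, adjusted p = 0.0113) and 15 of 39 proteasome subunits were more positive in CSN (29 when adjusted over the list alone). So were 8 of 22 autophagy and lysosome genes (10), such as Ctsd (1.22) and Ctsb (1.06), 7 of 27 ER-to-Golgi genes (13), such as Cope (0.93), and 5 of 26 unfolded protein response genes (9), such as Herpud1 (0.99), where brackets give counts adjusted over the list alone. More negative were 8 of 12 mitochondrial genome genes, such as mt-Nd4 (-1.15), and 3 of 12 GABAergic markers. The latter were Gad2 (-2.28), Gad1 (-2.09) and Slc32a1 (-0.65), and the counts adjusted over the list alone were 11 and 4. In control cells Gad2 had risen by 2.28, while the 9 GABAergic markers measured in CSN had a median of -0.000456, with 1 higher. A difference can thus come from control cells alone.

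Nuclear oxidative phosphorylation had 16 of 82 more positive (18 when adjusted over the list alone), such as Sdha (1.23), around a median of 0.15 that turned to -0.13 with quantile normalisation. Antioxidant and cholesterol synthesis genes had 1 each, Gsr and Sqle (4 and 4 when adjusted over the list alone), and ribosomal proteins had Rpl4 more positive (0.63) around a median of -0.23 that camera called lower (0 when adjusted over the list alone). With an estimated correlation these 10 lists had adjusted p = 0.18 to 0.85. The largest positive differences by the naming rule were Doc2a (1.73), Igsf21 (1.66), Panx1 (1.65), Zfp358 (1.64), Lhfpl5 (1.64), Mc4r (1.59), Prpf19 (1.59), Slc27a1 (1.57), Snapc2 (1.56) and Ddx56 (1.56). Igsf21 had fallen in control cells (-1.62), so its difference is not a rise in CSN alone. The largest negative ones were CT010467.1 (-1.44), Mir6240 (-1.40), Hsd3b2 (-1.38), mt-Rnr1 (-1.37), Olfr613 (-1.36), mt-Nd6 (-1.34), Vmn1r58 (-1.32), Mrgprc2-ps (-1.32), mt-Rnr2 (-1.28) and Frmpd3 (-1.26). Of the genes named for this difference, Rpl4, Sqle and CT010467.1 lost their calls without any 1 of 28 to 33 of the 57 libraries, and Doc2a, Zfp358, Mc4r, Mir6240, Olfr613 and Mrgprc2-ps without any 1 of 10 to 12. Herpud1, Gad1, Slc32a1, Slc27a1, Hsd3b2, Vmn1r58 and mt-Rnr2 lost theirs without any 1 of 3 to 7 (adjusted p up to 0.118 over these genes). Lhfpl5 lost its call without CSN Sod1G86R 30-day replicate 6 (0.0504) or wild-type control 60-day replicate 1 (0.0562), mt-Rnr1 without the latter (0.0504) and Frmpd3 without CSN Sod1G86R 105-day replicate 13 (0.0515).

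Beside these gene groups, the mitochondrial share went down in Sod1G86R CSN, with no such fall in control cells, and receptor genes stood at 440.1 ± 234 and 347 ± 285 ppm of the reads in Sod1G86R and wild-type control cells. The count of 1380 was 0 in limma with the mitochondrial share as a covariate or without the 60-day libraries, 1 with the receptor gene share or the number of detected genes, and 392 with no filter or with quantile normalisation (198 and 194 in the latter). It was 239 without wild-type control 60-day replicate 1 and 3050 without wild-type control 90-day replicate 3, and it moved by over 1.5 times without any 1 of 20 other libraries. Among control cells it was 821 and 2312 without Sod1G86R 105-day replicates 10 and 9, 2227, 768 and 747 without 30-day replicates 2, 3 and 4, 460 without 60-day replicate 3, and 783 and 2266 without 90-day replicates 3 and 8. In wild-type control cells it was 719 and 2165 without 105-day replicates 12 and 13 and 837 without 90-day replicate 7. In Sod1G86R CSN it was 329 and 533 without 105-day replicates 13 and 9, 330 without 30-day replicate 6, 680 without 60-day replicate 1 and 877 without 90-day replicate 6. In wild-type CSN it was 907 and 720 without 60-day replicates 2 and 3, and 857 and 784 without 90-day replicates 7 and 9.

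Age was compared in wild type between 105 and 30 days. In control cells Plekha1, an adaptor that binds membrane phosphoinositides, fell from 11770 ± 3700 to 3095 ± 1620 (-1.99, SE 0.32, adjusted p = 0.0193, n = 4 each), and Irf7, a transcription factor of the interferon response, from 789.4 ± 348 to 16.88 ± 16.3 (-3.91, SE 0.693, adjusted p = 0.0473). These made 2 of 20944 genes. Myelin genes were at lower values without passing, such as Mog (19510 ± 10700 against 87270 ± 18200; -2.33, adjusted p = 0.0604) and Mal (-2.25, adjusted p = 0.0604). In limma 0 of 12 oligodendrocyte markers passed over all genes and 12 were lower when adjusted over the list alone (median -2.17; camera adjusted p = 4.4e-16, adjusted p = 0.2 with an estimated correlation). Cholesterol synthesis genes had 0 of 18 and 8 lower when adjusted over the list alone (adjusted p = 0.3 with an estimated correlation). Medians of oligodendrocyte precursor, endothelial and mural cell and microglia markers were -1.83, -1.11 and 0.62, with 0 of 8, 14 and 14 passed in limma (4, 4 and 0 lower when adjusted over the list alone). The mitochondrial share was 1.45% ± 0.444 at 105 and 0.898% ± 0.0859 at 30 days, and receptor genes stood at 539 ± 314 and 253 ± 194 ppm of the reads. With the mitochondrial share as a covariate 0 genes passed in limma. Other values that did not pass were Gsn (-3.81) and Lyve1 (-3.44), and Bhlhe41 (1.86), Cst3 (1.49) and Fmc1 (1.49). Irf7 lost its call without any 1 of 7 and Plekha1 without any 1 of 5 of the 8 libraries. The count was 594 without 105-day replicate 12, where the other genes named here passed as well (adjusted p 0.00264 to 0.0235), and 0 without 105-day replicate 9, 11 or 13 or 30-day replicate 1 or 4, and 201 in DESeq2.

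In wild-type CSN, 0 of 19093 genes passed between 105 and 30 days in limma, with 1187 at an unadjusted p under 0.05, 0 in edgeR and 6 in DESeq2. The smallest p-values belonged to Gnpda2 (0.99), Alad (1.03), Nacc2 (0.98), Rnf122 (-2.34), Prom1 and Tmem94 (-0.88), each with adjusted p = 0.517. Oligodendrocyte markers had a median of -1.22 and immature neuron genes of -0.39, with 0 of 12 and 0 of 13 passed (1 and 3 lower when adjusted over the list alone), and adjusted p = 0.92 and 0.8 with an estimated correlation. Sod1 (-0.27) and Creb3 (0.34) did not pass. The count was 2 without 30-day replicate 3.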

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

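Chosen only after the result was seen were the tests of the chromosome 3 segment, the tests of Creb3 against the glial marker score, the reading of the glial score for astrocytes, oligodendrocytes and microglia alone, and the values with the mitochondrial share or receptor gene share as a covariate. The tests of library quality on the CSN genes were written before their own values were seen but after the effect of the mitochondrial share on the counts was known.

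In 11 groups of 4 libraries, 6 measures gave 66 tests of whether 1 library lies far from the other 3, and 5 exceeded Dixon's critical value, where chance gives about 1 in 20. Control Sod1G86R 90-day replicate 3 had 31.5 M recovered reads against 35.7 to 36.2 in the others. CSN Sod1G86R 90-day replicate 8 had a mitochondrial share of 7.645% against 2.986% to 3.485%. Creb3 in wild-type control 105-day replicate 12 was 7253 against 4257 to 4665. CSN wild-type 105-day replicate 13 had 38020 detected genes against 32810 to 33560, and CSN wild-type 60-day replicate 7 had 36.9 M reads against 26.0 to 27.4. At 90 days in CSN, leaving out replicate 8 raised the count of genes from 928 to 1983.

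The genotype effect differed between CSN and control cells, by a test of the difference itself, for 1380 genes. Creb3 differed by 0.8075. The named genes with a more positive effect in CSN were Doc2a (1.729), Igsf21 (1.664), Panx1 (1.651), Zfp358 (1.639), Lhfpl5 (1.638), Mc4r (1.594), Prpf19 (1.586), Slc27a1 (1.574), Snapc2 (1.563) and Ddx56 (1.559). Those with a more negative effect were CT010467.1 (-1.439), Mir6240 (-1.395), Hsd3b2 (-1.384), mt-Rnr1 (-1.374), Olfr613 (-1.356), mt-Nd6 (-1.342), Vmn1r58 (-1.322), Mrgprc2-ps (-1.321), mt-Rnr2 (-1.284) and Frmpd3 (-1.261). In limma 0 genes passed with the mitochondrial share as a covariate, against 1380 without it. A difference can come from either cell type, as for Igsf21, which fell in control cells (-1.62).

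The neighbouring genes on chromosome 3 were lower in both cell types. Library quality, as far as the mitochondrial share measures it, did not account for this. The median in CSN was -0.964 (quartiles -1.15 and -0.733) with that share as a covariate, against -0.972 (-1.22 and -0.628) without it. Recovered reads were higher in Sod1G86R CSN and lower in Sod1G86R control cells (log2 differences within ages 0.357 and -0.34). The segment's medians were below 0 in both cell types (-0.972 and -0.917), which argues against read depth as the cause in both. Other measures of quality were not tried as covariates on this median, so library quality in general is not excluded. The glial marker score as a covariate did not account for it either, with a median of -0.876 (-1.14 and -0.635). That score pools astrocytes, oligodendrocytes and microglia and covers no other cell types, so neither these cells nor others are excluded by it. Of 32 genes 28 were called, 15 with the mitochondrial share, where the median SE went from 0.17 to 0.191, and 26 with the glial score. Strain variants around the transgene cannot be told apart from a missing copy. In control cells 3.57% of the 28 segment genes with an unadjusted p under 0.05 lay above 0, but 27 of these 28 had been chosen by their lower values in CSN, largely of the same animals, so this decides nothing. A missing copy of the segment, 1 of 2, may underlie the pattern, but no DNA was examined and this stays a hypothesis. The position of the transgene was not examined either. The median of -0.917 in control cells has the same limit, as it covers largely the same chosen genes and animals. Single genes differed in CSN, such as Tram1l1 (-0.522, SE 0.12) and Fnbp1l (-1.31, SE 0.1).

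The genes called in CSN over the ages were taken outside Sod1, Gm8566 and the segment. Of these genes, 64% were still called with the glial marker score as a covariate, so the pooled score did not account for most calls. Astrocytes, oligodendrocytes and microglia are not excluded by it, as it pools them. With it in the fit, their markers had medians of 0.651, -0.0831 and -0.421. Cells of other types stay open as well, as the score does not cover them. Library quality remains open: 85.4% of these genes followed the mitochondrial share within wild-type libraries in the direction this would need, against 65.7% of other genes. With that share as a covariate 7 of 3603 were still called. The median effect in the direction of the call went from 0.497 to 0.282 and the median SE from 0.133 to 0.153, so calls ended through both a smaller effect and a larger error. The mitochondrial share may equally be changed by the genotype itself, which the design does not separate.

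Creb3 in CSN was not told apart from library quality. With the mitochondrial share as a covariate its log2 fold change was 0.351 (SE 0.135, limma adjusted p = 0.326). Its correlation with that share over the 16 wild-type CSN libraries, within ages, was weak and uncertain, so it decides nothing. Pearson's r was -0.316 (permutation p = 0.155), Spearman's rho -0.344 (permutation p = 0.193), and r was -0.347 without the 2 libraries farthest from the median, with 1 relation computed. The glial marker score did not account for the rise, since Creb3 was 0.671 (SE 0.129) without and 0.615 (SE 0.141, adjusted p = 0.00551) with it as a covariate. As the score pools astrocytes, oligodendrocytes and microglia, these cells are not excluded by it. The score itself differed by -0.719 within ages in CSN (permutation p = 0.0479, adjusted p = 0.0669), which decides nothing for cells of other types, and these stay open. An effect of the genotype on Creb3 stays among the open explanations.

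Other splits of the same libraries were fitted for each comparison with at least 3 libraries per group. Only the real split called as many genes for CSN at 90 days (928 genes, highest other split 1, 1 of 35 splits as large). The same held for CSN over the ages (3643, highest other 3125, 1 of 100). It also held for control cells at 90 days (2, highest other 1, 1 of 35) and over the ages (15, highest other 10, 1 of 100). The difference between cell types (1380, highest other 504, 1 of 100) and CSN against control cells (12405, highest other 4081, 1 of 100) were alike. The real split is counted, so no share could be lower, and the shares were not adjusted over the comparisons. They make chance less likely but do not exclude it. For control cells at 90 days the 2 genes were Sod1 and Gm8566, which follow the transgene, so that split adds nothing. For control cells over the ages the 15 genes included Sod1, Gm8566 and 7 genes of the chromosome 3 segment. In CSN over the ages another split, beside the one with 3125, called 2699. These 2 splits exchanged 8 and 10 of 29 libraries, with log2 differences of the mitochondrial share of -0.488 and -0.425 against -0.635 in the real split, so they are not independent of genotype. Splits that also exchanged 8 and 10 libraries, with differences of -0.447 and -0.444, called 5 and 0 genes in limma, so what gives the 3125 and 2699 is left open. Other splits called as many genes or more for CSN at 30 days (3, highest other 205, 5 of 35) and 60 days (6, highest other 300, 2 of 35). The same held for control cells at 30 days (2, highest other 6, 5 of 35) and 105 days (2, highest other 6, 5 of 35). It also held for age in wild-type control cells (2, highest other 697, 2 of 35). For these counts of genes chance stays open, but a count does not weigh single genes. Sod1 and Gm8566 were among the calls in these genotype comparisons. There Sod1 was 24.6- to 41.6-fold higher, with every Sod1G86R library above every wild-type library, which argues against chance for Sod1. For genotype by age and for age in wild-type CSN limma called 0 genes, so every split is as large (100 of 100 and 35 of 35, highest other 2 and 85) and the splits decide nothing. What gives the 205, 300, 85 and 697 genes in other splits was not tested. CSN at 105 days and control cells at 60 days have a group of 2 and were not split.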

How the results depend on the processing

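The mitochondrial share and receptor gene share as covariates, the fits without the 60-day or 90-day libraries and the ALS-linked list without Sod1 were chosen after the data had been seen; every other alternative was set before the data were examined, and of these a Y-linked covariate was not run. Of 21252 values of 567 gene results under alternatives, 19302 kept direction and side of the threshold, 1529 lost the call, 402 gained a call and 19 changed sign. These totals pool leave-one-out fits and genes that had not passed, and comparisons differed. Leave-one-out and other values that lost the call were 199 of 416 and 148 of 830 for CSN at 90 days. They were 269 of 3477 and 249 of 975 for the difference, and 0 of 3420 and 0 of 1368 between cell types. For each count below, the cause was not tested. Counts are of genes at an adjusted p under 0.05.

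Without filter the counts were 4 (CSN at 90 days), 2173 (CSN over ages), 4 (control at 30 days), 75 (control at 60 days), 8 (control over ages), 392 (difference between cell types) and 0 (age in control cells; edgeR 0, DESeq2 201). The stricter filter gave 8 (CSN at 30 days), 478 (control at 60 days), 36 (control over ages) and 18 (age in control cells). A pseudocount 0.25 times as large gave 156 (control at 60 days) and 1 (age in control cells), and 1 that was 4 times as large gave 6 (control at 30 days), 617 (control at 60 days), 55 (control over ages) and 1 (age in control cells). Quantile normalisation gave 11 (CSN at 30 days), 440 (CSN at 90 days), 392 (difference between cell types) and 1 (age in control cells). With it Stmn2 in CSN turned to -0.006129, Sod1 in the difference to -0.1837 and Tle4 between cell types to 0.06279.

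Array weights gave 7, 1916 and 15 in CSN at 30, 90 and 105 days, 24 and 2455 in control cells at 30 and 60 days, 1.5e+02 over ages (22 of them higher), 3230 for the difference and 533 for age in control cells. Detected genes as a covariate gave 604 (CSN at 90 days), 1582 (CSN over ages), 6 (control at 60 days), 5 (control over ages), 1 (difference) and 0 (age in control cells), with Creb3 in control cells over ages at 0.02289. The glial marker score gave 6 (CSN at 30 days), 2 (control at 60 days) and 9 (age in control cells). With it, at 60 days in control cells, Cnp turned to 0.4422 and Mbp to 0.3944, and over ages Creb3 turned to 0.02498, Ermn to 0.02124, Cx3cr1 to 0.02935, P2ry12 to 0.0203 and Ppp1r15a to 0.001538. Library number gave 638 (control at 60 days), 28 (control over ages) and 9 (age in control cells).

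The mitochondrial share gave 3, 5 and 25 in CSN at 60 and 90 days and over ages, 4 and 6 in control cells at 60 days and over ages, and 0 for the difference and for age in control cells in limma, with Creb3 in control cells at 0.09512. The receptor gene share gave 4 and 39 in CSN at 90 days and over ages, 7 in control cells over ages and 1 for the difference. With it Cnp in CSN turned to 0.07264, Creb3 in control cells to 0.03266, and in the difference Hsd3b2 to 0.04901, Olfr613 to 0.1456, Vmn1r58 to 0.04077 and Mrgprc2-ps to 0.1083. Without the 60-day libraries the counts were 8 in control cells over ages, with Creb3 at 0.09058, and 0 for the difference, and without the 90-day libraries 1118 in CSN over ages. The 0 counts here stand beside 5794 genes of the difference and 2627 of age in control cells at an unadjusted p under 0.05 without covariates, 1804 and 0 in edgeR and 3067 and 201 in DESeq2.

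Fitting only the libraries of the groups compared gave 2 and 2 in CSN at 60 and 105 days, 6 in control cells at 60 days and 48 for age in control cells. A replicate block by age and number, as a paired alternative, gave 28, 11, 1846 and 7 in CSN at 30, 60, 90 and 105 days and 5 and 25 in control cells at 30 days and over ages. Libraries of a number and age are not of 1 animal across genotypes. Their residual correlation was over 0.1 in 5 of 9 pairs in CSN (-0.048 to 0.493, median 0.249) and 2 of 7 in control cells (-0.161 to 0.413, median -0.0422). The consensus correlation of the block was 0.269 in CSN and 0.0486 in control cells. The numbers were not taken as pairs in the main fits, which leave out any condition that they share in CSN. Of 18 such CSN libraries 10 correlated best with their own number, as did 4 of 14 of control cells, a hint of shared conditions in some pairs. On recovered reads edgeR gave 2 (CSN at 105 days), 84 (control at 60 days) and 0 (age in control cells). DESeq2 gave 284, 14, 1932 and 23 in CSN by age, 2 for genotype by age, 41, 2239, 8, 9 and 174 in control cells by age and over ages, 3067 for the difference, and 6 and 201 for age in CSN and control cells. For gene lists, 176 calls became 2 with an estimated correlation and 60 by fry, and the ALS-linked list in CSN over ages went to adjusted p = 0.18 without Sod1.

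Leaving out 1 library at a time gave 3 to 42, 3 to 6, 4 to 1983 and 2 to 4 genes in CSN by age, 2222 to 4377 over ages and 0 to 0 for genotype by age in limma. It gave 2 to 5, 1 to 501, 2 to 2 and 2 to 3 in control cells by age and 7 to 58 over ages, 239 to 3050 for the difference, 11204 to 12506 between cell types, and 0 to 2 and 0 to 594 for age in CSN and control cells. The libraries behind these ranges are named beside each result in the report. A group left with 1 library is assumed to vary like the others. Simulated changes of 2-fold were recovered for 1% to 75% of genes, so a gene that did not pass is not shown to be the same.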

Other observations

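The scan along chromosomes was chosen only after the result was seen. It scored runs of neighbouring genes by their lower values in Sod1G86R CSN over 12915 genes. The chromosome 3 segment scored 14.28, where the highest of 1000 shuffles of gene order was 2.384. Shuffling breaks any correlation between neighbouring genes, and the score uses the values that set the segment. The shuffles therefore show only that lower genes cluster there. A run on chromosome 9 (3000282 to 3038316, 10 genes) scored 7.553 and a run on chromosome 11 (81860673 to 82103400, 4 genes) scored 3.025, and neither was examined further. The median of the chromosome 3 segment in CSN was -0.846, -1.05, -0.821 and -1.07 at 30, 60, 90 and 105 days, and in control cells -0.947, -0.574, -0.787 and -1.08.

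Recovered reads differed between genotypes, with 40.7 ± 10.3 M in Sod1G86R CSN (n = 13) and 32.3 ± 6.89 in wild-type CSN (n = 16; permutation p = 0.00226, adjusted p = 0.00753), and 34.2 ± 7.92 against 42.2 ± 8.15 M in control cells (n = 14 each; permutation p = 0.00758, adjusted p = 0.019). Detected genes numbered 31520 ± 2390 against 33300 ± 2290 in CSN (permutation p = 0.06) and 37280 ± 2710 against 34930 ± 4310 in control cells (permutation p = 0.0516), each with adjusted p = 0.0669.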
